A study of Mus musculus with 4 samples.

How the data were processed

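Gene expression was measured by Drop-seq in 4 libraries of primary Gli1-positive kidney cells, 1 per time point: a control after 2 h without serum, labelled 0 h, and cultures given 1 ng/ml TGF-β for 6, 12 and 24 h. Per the labels, cells were detached for 10 min and about 5000 cells were estimated to have been prepared. The deposited table holds whole-number counts per gene and barcode, not normalized, for 17391 genes and 3298 barcodes, and column names give each barcode's library. The unit was read from the values, which are whole numbers, and whether UMIs were collapsed is not stated, so they are called counts here. Per the submitters' processing notes, reads were aligned with STAR 2.5.3a to mm10. The counter, the annotation, the barcode filter and the strand setting are not given in the sources used here. All deposited barcodes had 200 genes or more and under 5% mitochondrial counts, as found in the table.

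Barcodes with 200 genes or more and at most 20% mitochondrial counts were kept, which removed none. Of 17391 genes, 375 had no count. Barcodes 1 base away from another barcode of their library numbered 0, 18, 257 and 277 in time order, against 0.0787, 0.928, 2.69 and 3.78 by chance, so some cells may be split over barcodes, and no barcodes were merged. Scrublet, as in scanpy, called 33, 9, 18 and 14 barcodes doublets. They were kept, and leaving them out was an alternative. Counts were summed per library and scaled to CPM. Log2 ratios are of CPM plus a pseudocount of 10, which understates the differences of low genes. Ratios without a pseudocount are ratios of CPM with exact conditional binomial 95% intervals. CPM intervals are exact Poisson, and intervals of shares are exact binomial. With 1 library per time point no test was made. For a gene without a count, a bound of 3 counts in that library was used and the ratio is given as at least that size.

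Counts of genes cover those at 100 CPM or more in either library and at least 2-fold apart. For these, 100 pairs of libraries were redrawn from 1 profile to count genes passing by counting error alone. The comparisons are each treated library with the library labelled 0 h, and consecutive time points. For each of the 36 gene lists, the median log2 ratio over members with a mean of 20 CPM or more was set beside 10000 random lists matched on expression in 20 bins. Among treated libraries the mean over the 3 treated libraries was used. The 9 cell type marker lists were summed. Named genes are the 12 highest and 12 lowest by log2 ratio at 100 CPM or more in either library, leaving out mitochondrial, ribosomal protein, predicted and unnamed genes. Genes fixed in advance, among them Gli1, Acta2, Tagln, Col1a1, Col1a2, Col3a1, Fn1, Postn, Ctgf, Pdgfra, Pdgfrb, Mki67 and Malat1, were to be named as well, and each list could add up to 4 members with the largest absolute log2 ratio of each list. Shares of barcodes were compared after thinning to 500 counts, the depth set for the case that over 50% of a library's barcodes had fewer than 1000 counts. Clustering used log values scaled to 10000 counts, 2000 variable genes, 30 components, 15 neighbours and Leiden at resolution 0.5. The groups, comparisons, lists, rules and alternatives were chosen before the data were examined, except for 24 h against 6 h, the use of the list and naming rules among treated libraries, barcodes with 1000 or more counts, and genes sharing 3′ sequence.

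Gene positions and overlaps come from GENCODE M21, the annotation available here. Shared sequence was sought as 51-mers in the last 600 bases of transcripts, and reads could not be realigned. Alternatives were stricter barcode filters (500 genes, 10% mitochondrial), TMM and DESeq2 size factors, totals without mitochondrial and ribosomal protein genes, equal weight per barcode, pseudocounts of 1 and 50, floors of 50 and 200 CPM, a 1.5-fold limit, subsets of barcodes, totals thinned to the shallowest library, list members at 50 CPM, other thinning depths and other clusterings. The method was tested on simulated data at the depths of these libraries. Of 100 genes changed 4-fold, 94% to 100% were found, of 100 changed 1.3-fold, 0% to 4%, and of unchanged genes, 0% to 2.47%. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.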

Results

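Gene expression was measured in single cells by Drop-seq, which captures cells in droplets with barcoded beads, in primary cultures of Gli1-positive kidney cells from male mice aged 12 weeks. Gli1 marks mesenchymal cells around vessels and tubules that form myofibroblasts in kidney fibrosis. The cultures spent 2 h without serum and then received 1 ng/ml TGF-β, a cytokine that drives myofibroblast formation, for 6, 12 or 24 h. A control, labelled 0 h, was harvested after the serum-free period and received no TGF-β. The series asks how these cells change on the way to a myofibroblast state. Each time point had 1 library, so no difference below has a replicate check, and every value describes the libraries compared. Hours with TGF-β and hours without serum go together, because no untreated culture was sampled at 6, 12 or 24 h.

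The libraries differed strongly in depth. The library labelled 0 h held 192 barcodes and 106826 counts, with a median of 489.5 counts per barcode. The 6 h library held 658 barcodes and 778793 counts, with a median of 313.5. The 12 h library held 1120 barcodes and 5687966 counts, with a median of 3815.5, and the 24 h library held 1328 barcodes and 6166324 counts, with a median of 3379. In the 6 h library 79.6% of barcodes had fewer than 500 counts, while 80 barcodes with 1000 or more counts held 74.1% of all its counts. A gene without a count could still be present at up to 28.1 CPM, which is counts scaled to 1 common total for every library, in the library labelled 0 h, 3.85 CPM at 6 h, 0.527 CPM at 12 h and 0.487 CPM at 24 h. Ranges in parentheses are exact 95% intervals, which cover counting error only.

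**Figure D1:**
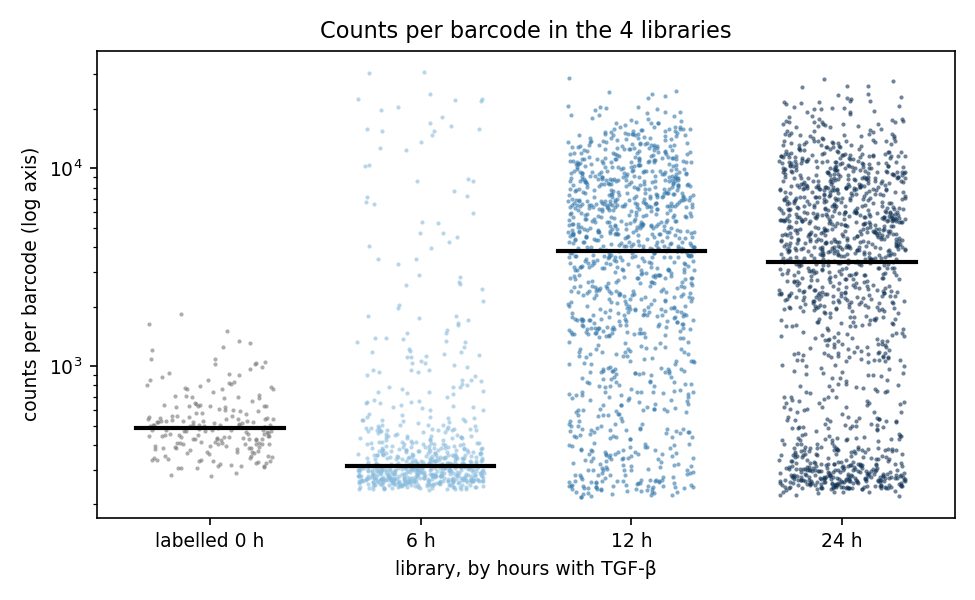
Counts per barcode on a log axis in each library, by hours with TGF-β; each point is 1 barcode and each black line a library's median. The medians are 489.5 in the library labelled 0 h, 313.5 at 6 h, 3815.5 at 12 h and 3379 at 24 h.

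The content of the library labelled 0 h went against its label. Transcripts of kidney tubules were among its most abundant. Acsm2, a kidney acyl-CoA synthetase, had 552 counts. Slc34a1, the phosphate transporter of the proximal tubule, had 454, Slc12a1, the salt transporter of the loop of Henle, had 276, and Kap, a proximal tubule androgen-regulated gene, had 206. The proximal tubule marker list summed to 10681 CPM (10070 to 11319), against 19.3 CPM (10.8 to 31.8) at 6 h and 23.8 CPM (20.1 to 28.0) at 24 h. The list for loop of Henle, distal tubule and collecting duct summed to 3632 CPM (3280 to 4012), against 6.42 CPM (2.08 to 15.0) at 6 h. Endothelial markers summed to 346 CPM (244 to 477) and macrophage markers to 131 CPM (71.6 to 220), against 5.14 CPM (1.40 to 13.2) and 7.70 CPM (2.83 to 16.8) at 6 h. Schwann and neural markers summed to 46.8 CPM (15.2 to 109), lymphocyte markers to 18.7 CPM (2.27 to 67.6), and the single measured erythroid marker had no count. Podocyte markers summed to 243 CPM (159 to 357) there and to 175 CPM (165 to 186) at 24 h, where 172 CPM came from Synpo alone.

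Mesenchymal transcripts were nearly missing from that library. The mesenchymal list summed to 46.8 CPM (15.2 to 109), against 2687 CPM (2574 to 2805) at 6 h, 5581 CPM (5520 to 5643) at 12 h and 6826 CPM (6761 to 6891) at 24 h. Col1a1, Col3a1, Acta2, Fn1, Sparc and S100a6 had no count in it, and Col1a2 had 3. Malat1, a nuclear RNA, took 32.2% of its counts, against 0.947% at 6 h, 1.13% at 12 h and 1.24% at 24 h. Ribosomal protein genes took 0.355%, against 15.7%, 11.1% and 15.6%. Across 1949 genes, its log expression had Pearson's r of 0.13 with the 6 h library, 0.14 with 12 h and 0.09 with 24 h, while the treated libraries had r of 0.86 to 0.95 with each other. These correlations are across genes, which are not independent replicates. Directions drawn from the library labelled 0 h are therefore given below only as differences between libraries.

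**Figure D2:**
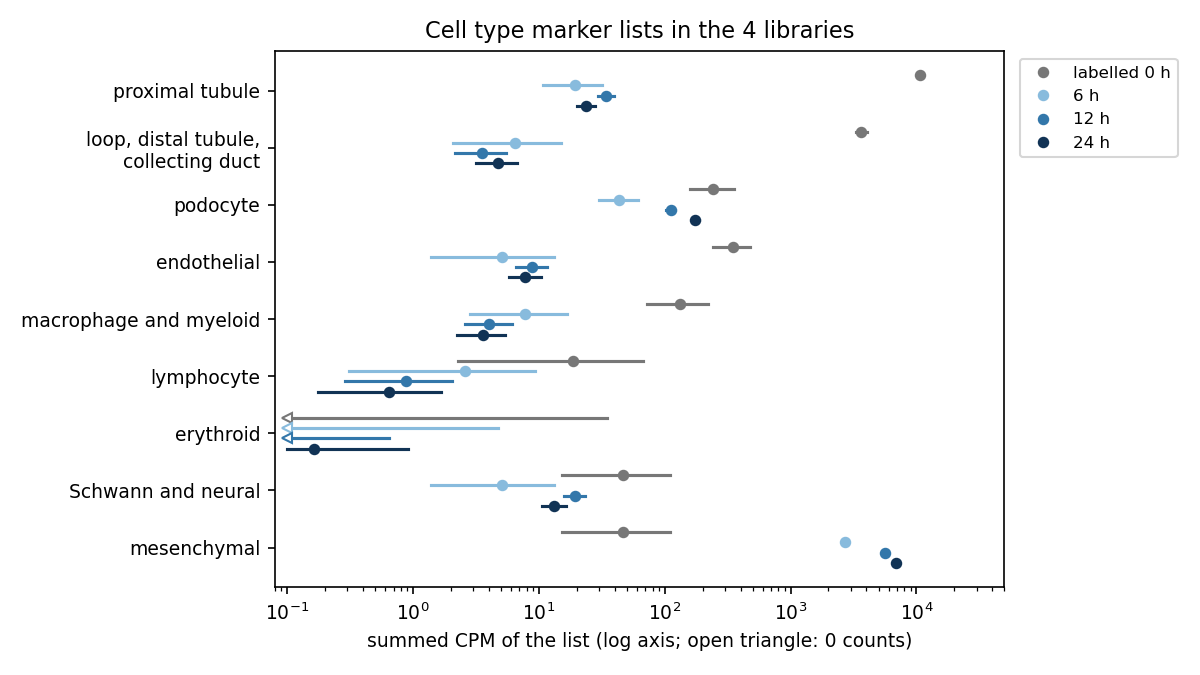
Summed CPM of the cell type marker lists on a log axis, for each library; points are sums, lines are exact 95% counting intervals, and an open triangle marks a sum of 0 counts. Proximal tubule markers sum to 10681 CPM in the library labelled 0 h and to 23.8 CPM at 24 h, and mesenchymal markers to 46.8 and 6826 CPM.

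The comparisons of each treated library with the library labelled 0 h were planned to ask which genes TGF-β changes. Given the tubule content of that library, the values cannot answer this and only describe how the libraries differ. The highest genes were of several kinds. S100a6, a calcium-binding protein, was at least 275-fold higher at 6 h, at least 197-fold at 12 h and at least 145-fold at 24 h. Fn1, the matrix glycoprotein fibronectin, was at least 102-fold higher at 12 h and at least 120-fold at 24 h. Sparc, a collagen-binding matrix protein, was at least 78.2-fold higher at 12 h and at least 93.0-fold at 24 h. Lgals1, Actb and Vim were among the 12 highest at every time, and each had 1 or 2 counts in the library labelled 0 h against 8446, 5006 and 3476 CPM at 24 h. S100a4, Prl2c2, Timp1, Npm1, Tmsb4x and Serpinb6a also led at 6 h. Ctla2a, Fbln2, Meg3 and Nupr1 led at 12 h, and Fstl1 and Ankrd1 at 24 h. Tpt1 led at 6 and 24 h.

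Tubule transporter genes were among the lowest. Slc34a1 was at least 1103-fold lower at 6 h, at least 8058-fold at 12 h and at least 8735-fold at 24 h, and Kap at least 501-, 3656- and 3964-fold. Acsm2, Slc12a1, Nlrp6, Slc7a13, Slc27a2, Slc22a30, Snhg11, Maf, Mlxipl and Fut9 made up the rest of the 12 lowest at each time. At 6 h 1393 genes were at least 2-fold higher and 954 lower among 2832 genes at 100 CPM or more in either library. At 12 h the counts were 1516 and 884 of 2953, and at 24 h 1419 and 928 of 2875. The balance depended on the barcodes: with at least 500 genes per barcode there were 1375 higher and 1515 lower at 6 h, 1472 and 1469 at 12 h, and 1378 and 1543 at 24 h. In barcodes with 1000 or more counts there were 1367 and 1322, 1472 and 1284, and 1389 and 1356. The library labelled 0 h had only 13 such barcodes, with 15.4% of its counts. In them 1 count, as for Ctgf, amounted to 61.0 CPM, so very few counts took a gene past 100 CPM. The median of all these genes was itself off 0, at 0.89, 1.11 and 0.95 on the log2 scale, and TMM scaling moved it to 1.22 at 6 h and 1.27 at 24 h.

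Among the gene lists fixed for this tissue, ribosomal protein genes stood highest against the library labelled 0 h. Their median log2 ratio was 5.14 at 6 h, 4.55 at 12 h and 5.11 at 24 h, above every one of the matched random lists. At 24 h the median was 3.91 for matrix glycoproteins and proteoglycans (18 of 18 measured members higher by 1.5-fold), 3.68 for contractile genes (14 of 16), 2.62 for collagen processing (17 of 19), 2.01 for collagens (8 of 13) and 2.23 for TGF-β target genes (14 of 20). With genes lacking a count set to the level a count of 0 allows, these medians were 2.67, 3.54, 1.85, 1.70 and 0.67. Chemokines and cytokines had a median of 3.95, or 2.28 with that bound. S phase genes had a median of 0.65 and G2 and M phase genes of 0.46, which turned to -0.12 and -0.72 with that bound. Nuclear-retained RNAs had a median of -3.08, with Malat1 and Neat1 lower and Meg3 higher. The median over all 6910 measured genes was 0.59.

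Most of these differences were shared by the time points. Of 3189 genes at 100 CPM or more in any library, 1527 were at least 2-fold higher and 849 lower at 6, 12 and 24 h alike. A further 53 genes differed by 2-fold at 6 h and lay within 1.5-fold at 24 h, and 35 did the reverse. At 6 and 24 h, 2423 genes passed in the same direction. Unchanged libraries drawn from the profile of the library labelled 0 h gave a mean of 22.8 such genes, and independent lists would share 835 higher and 279 lower genes. These comparisons share 1 control library, which cannot be split into controls. It had Pearson's r of 0.09 to 0.14 with the treated libraries, which had 0.86 to 0.95 with each other. Calls against so different a library would be largely shared in any case, so neither count tests a course over time.

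From 6 h to 12 h the matrix genes were higher. These comparisons between treated libraries do not use the library labelled 0 h. Collagens had a median log2 ratio of 1.02, above all 10000 matched random lists, with 9 of 12 measured members at least 1.5-fold higher and none lower. Col3a1, the fibrillar collagen of reticular fibres, had 27.0 CPM (16.7 to 41.2) at 6 h and 173 CPM (162 to 184) at 12 h, 6.40-fold (4.17 to 10.4) more. Col1a2 was 2.66-fold (2.48 to 2.87) higher and Col1a1 2.51-fold (2.12 to 3.00), both chains of type I collagen. Matrix glycoproteins had a median of 0.96, with 14 of 18 members higher and 1 lower. Fn1 had 745 CPM (685 to 808) and 2862 CPM (2818 to 2906), 3.84-fold (3.54 to 4.18) more. Ltbp2 and Ltbp3, which bind latent TGF-β or microfibrils, were 7.76-fold (4.41 to 15.1) and 6.45-fold (4.24 to 10.3) higher. Collagen processing genes had a median of 0.91, with 14 of 19 higher and none lower. Bmp1, which cleaves procollagen, was 5.40-fold (3.76 to 8.04) higher, and the crosslinking enzymes Loxl1 and Loxl2 3.54-fold (2.36 to 5.56) and 2.84-fold (2.41 to 3.36).

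Genes of several other kinds were higher too. Piezo2, a mechanically gated channel, led all named genes at 8.99-fold (6.28 to 13.4). Gadd45a, a stress and growth arrest gene, was 6.16-fold (4.45 to 8.78) higher, the chemokine Ccl7 6.34-fold (4.04 to 10.6), the adhesion molecule Vcam1 5.23-fold (3.81 to 7.39), Prss23 5.13-fold (3.98 to 6.73), Nupr1 4.63-fold (4.05 to 5.30) and Anxa8 4.18-fold (3.08 to 5.80). TGF-β target genes had a median of 0.65 with 11 of 20 members higher, including Junb at 3.62-fold (2.48 to 5.48) and Nox4 at 3.89-fold (2.24 to 7.37). Chemokines had a median of 0.60, with 7 of 13 higher and 2 lower. Matrix proteases and their inhibitors had 0.88, Wnt pathway genes 1.02, lysosome genes 0.52, p53 targets 0.58, cholesterol synthesis 0.56, growth factors and IGF binding proteins 0.61, YAP targets 0.41 and integrins 0.42. Each of these medians lay above the central 95% of its matched random lists and stayed above 0 with TMM and DESeq2 scaling.

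Cell cycle genes were lower at 12 h. G2 and M phase genes had a median log2 ratio of -1.12, below all matched random lists, with 29 of 40 members at least 1.5-fold lower and 1 higher. Mki67, a marker of cycling cells, was 3.83-fold (3.17 to 4.61) lower, from 31 barcodes at 6 h of which 1 held 36 of 174 counts. Hmgb2 was 5.14-fold (4.06 to 6.49) lower, with 29 of its 126 counts at 6 h in 1 barcode, and Nusap1 7.76-fold (5.43 to 11.1). S phase genes had a median of -0.91 with 11 of 17 lower and none higher, including Pcna, the replication clamp, at 2.33-fold (1.95 to 2.78). Smaller shifts, below the central 95% of matched random lists and under 1.5-fold, were seen for NRF2 antioxidant genes at -0.47 (7 of 16 members lower, none higher), ATF4 and amino acid supply genes at -0.27 (6 of 15 lower, 1 higher) and glycolysis at -0.30 (3 of 13 lower, 1 higher). Gclm, of glutathione synthesis, was 4.58-fold (3.82 to 5.47) lower, with 34 of its 203 counts at 6 h in 1 barcode. The serine synthesis enzymes Psph, Phgdh and Psat1 were 3.92-fold (3.02 to 5.05), 2.84-fold (2.19 to 3.65) and 2.72-fold (1.99 to 3.68) lower. Nupr1, in the same ATF4 list, was higher.

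Acta2, the smooth muscle actin that defines myofibroblasts, was 5.38-fold (4.77 to 6.07) lower at 12 h than at 6 h, at 112 CPM (104 to 121) against 603 CPM (550 to 661). At 6 h it was counted in 126 barcodes, 1 of which held 81 of its 470 counts. The contractile list went both ways. Of its 15 measured members, Acta2 included, 4 were at least 1.5-fold higher, 2 lower and 9 between, with a median of 0.28 that lay within the central 95% of matched random lists. Actn1 was 2.74-fold (2.39 to 3.15) and Myh9 2.39-fold (2.13 to 2.70) higher, while Tagln, too low to be measured in the list, was 3.87-fold (1.52 to 9.17) lower from 9 counts at 6 h. Myl6, a myosin light chain outside the list and chosen after its values were seen, was at 1635 CPM at 6 h and 566 CPM at 12 h. Sec61g, Atp5l, Atp5g2, Morf4l1, Eif3j1, Lrrc58 and Xirp2 were further lower named genes. The largest difference, Oip5, rested on 1 barcode that held 895 of its 905 counts at 6 h, and Ap3s2 was counted in 24 barcodes at 6 h, 1 of which held 333 of its 793 counts. In barcodes with 1000 or more counts Ap3s2 was higher at 12 h, at a log2 ratio of 0.88, and at 0.89 with the stricter barcode filter. Oip5 and Nusap1 overlap on opposite strands, and the strand setting of the counting is not given in the sources used here. Ribosomal protein genes had a median of -0.53, with 37 of 80 members lower and none higher.

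In all, 108 genes were at least 2-fold higher and 98 lower at 12 h than at 6 h among 2256 genes. Libraries redrawn with counting error alone gave 0 such genes in each of 100 draws. These draws leave out unevenness between barcodes, such as the 1 barcode with 895 of 905 Oip5 counts at 6 h. They therefore speak to counting error only and not to other differences between single libraries. Higher genes made up 52.4% of these calls, but 36.7% with TMM scaling, 27.2% with DESeq2 size factors, 42.3% with mitochondrial and ribosomal protein genes left out of the total, and 67.9% when each barcode weighed the same. The all-gene median moved from 0.11 to -0.03 with TMM and to -0.11 with DESeq2. Among barcodes with 1000 or more counts, the medians were 0.74 for collagens, 0.74 for matrix glycoproteins and -1.19 for G2 and M phase genes.

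**Figure D3:**
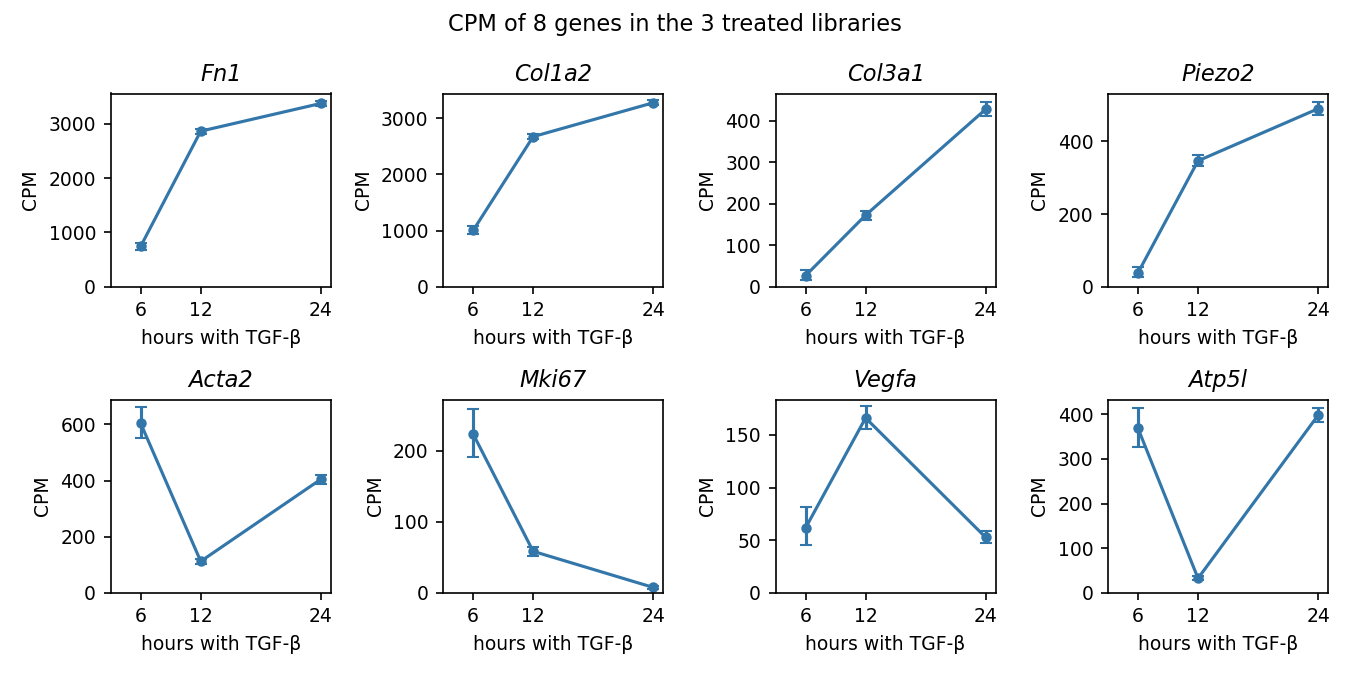
CPM of 8 genes in the 6, 12 and 24 h libraries; points are library values and bars are exact 95% Poisson intervals for counting error. Fn1 is at 745, 2862 and 3372 CPM, Mki67 at 223, 58.4 and 7.62 CPM, and Acta2 at 603, 112 and 404 CPM.

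From 12 h to 24 h the matrix genes stayed close to their 12 h level, with exceptions among single genes. The medians were 0.04 for collagens, -0.04 for matrix glycoproteins and 0.06 for collagen processing. Col3a1 was a further 2.48-fold (2.30 to 2.67) higher and Col8a1 1.90-fold (1.69 to 2.14), while Col7a1, of anchoring fibrils, was 1.84-fold (1.52 to 2.25) lower. The aggrecanase Adamts5 was 4.29-fold (3.59 to 5.16) higher. Acta2 was 3.60-fold (3.30 to 3.94) higher than at 12 h but 1.49-fold (1.35 to 1.65) lower than at 6 h. Cholesterol synthesis genes had a median of 0.47, above all matched random lists, with 5 of 16 members higher and none lower. Lss was 2.13-fold (1.77 to 2.57) higher and Fdps 1.98-fold (1.72 to 2.28), both enzymes of the sterol pathway. Tpm1, a tropomyosin, was 1.55-fold (1.51 to 1.59) higher, and the contractile list had a median of 0.28.

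Cell cycle genes were lower again at 24 h. G2 and M phase genes had a median of -0.91 with 25 of 40 members lower and none higher, including Hmmr at 11.6-fold (8.27 to 16.6) and Tpx2 at 12.2-fold (8.20 to 18.8). S phase genes had a median of -0.36. Has2, a hyaluronan synthase, was 3.40-fold (2.94 to 3.94) lower and the hyaluronan receptor Cd44 2.20-fold (2.03 to 2.39). Vegfa, an angiogenic growth factor, was 3.15-fold (2.78 to 3.59) lower, Prl2c2, a proliferin, 2.79-fold (2.68 to 2.91), Junb 3.10-fold (2.69 to 3.58) and the integrin Itgb3 2.52-fold (2.18 to 2.92). Pdlim5, Ecm1, Frmd6, Hnrnpa1, Ank and Nid1 were between 2.20- and 2.74-fold lower. TGF-β target genes had a median of -0.23, with 7 of 20 members lower and none higher. Hypoxia genes had -0.48, NRF2 genes -0.31, ATF4 genes -0.31, integrins -0.26 and matrix proteases -0.29, where the median of all genes was -0.11. With TMM scaling the integrins had -0.14, matrix proteases -0.15 and TGF-β target genes -0.09. Immediate early genes had -0.10, within the central 95% of matched random lists, and 0.02 with DESeq2 size factors. Nqo1, an NRF2 target, was 5.26-fold (3.83 to 7.36) lower.

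At 24 h against 12 h, 29 genes were at least 2-fold higher and 15 lower among 2146 genes. Counting error alone, without unevenness between barcodes, gave 0 in each of 100 draws. Higher genes made up 65.9% of these calls, 85.7% with TMM scaling and 85.4% with DESeq2 size factors, which moved the all-gene median from -0.11 to 0.03 and 0.04. They made up 51.3% at a floor of 50 CPM, 56.2% without genes sharing 3′ sequence, and 32.8% when thinned to the shallowest library, so the balance depended on the setting. Sec61g, Atp5l, Atp5g2, Morf4l1, Gng5, Sdpr, Lrrc58, Eif3j1 and Fabp5 were among the 12 highest, and all 9 had been lower at 12 h than at 6 h. Ribosomal protein genes likewise had a median of 0.54, with 35 of 80 members higher. In all, 27 genes were at least 2-fold lower at 12 h than at both 6 and 24 h, Acta2 among them, and 4 genes, chosen after their values were seen, had the opposite course: Ank, Ecm1, Junb and Vegfa. Thinned to the total of the shallowest library, in a single random draw that left Vegfa few counts, Vegfa had a log2 ratio of 0.22 and the hypoxia list, which holds Vegfa, a median of 0.22 at 24 h against 12 h.

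Across 24 h against 6 h, a comparison added after the data were examined, 108 genes were at least 2-fold higher and 88 lower among 2166 genes. Col3a1 was 15.9-fold (10.4 to 25.7) higher, Piezo2 12.7-fold (8.88 to 18.9), Prss23 9.65-fold (7.50 to 12.6), Medag 17.3-fold (7.90 to 47.2), Nupr1 7.54-fold (6.61 to 8.64) and Fstl1 4.88-fold (4.34 to 5.50). Adamts5, Ccl7, Ltbp2, Ltbp3, Vcam1 and Fn1 were the other leading genes, 4.53- to 12.3-fold higher. Hmmr was 38.1-fold (26.8 to 55.6) lower, Tpx2 33.7-fold, Mki67 29.3-fold (21.1 to 41.4), Cenpf 29.4-fold (20.5 to 43.1), Top2a 12.3-fold (9.89 to 15.4), and Cenpe, Prc1, Kif23 and Birc5 14.5- to 21.7-fold. Single barcodes at 6 h held 42 of 145 Cenpf counts and 30 of 112 Prc1 counts. Oip5, Ap3s2 and Xirp2 were among the 12 lowest as well, but Ap3s2 had a log2 ratio of 0.46 in barcodes with 1000 or more counts and 0.48 with the stricter barcode filter. G2 and M phase genes had a median of -2.44 with 32 of 40 members lower and none higher. Collagens had 1.05, contractile genes 0.58 and cholesterol synthesis 0.93, with 14 of 16 members higher. BMP pathway genes had -0.46, from 4 members, with Bmp2 3.74-fold (2.54 to 5.43) lower. Higher genes made up 55.1% of the calls, 47.5% with DESeq2 size factors, and 66.4% when each barcode weighed the same.

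**Figure D4:**
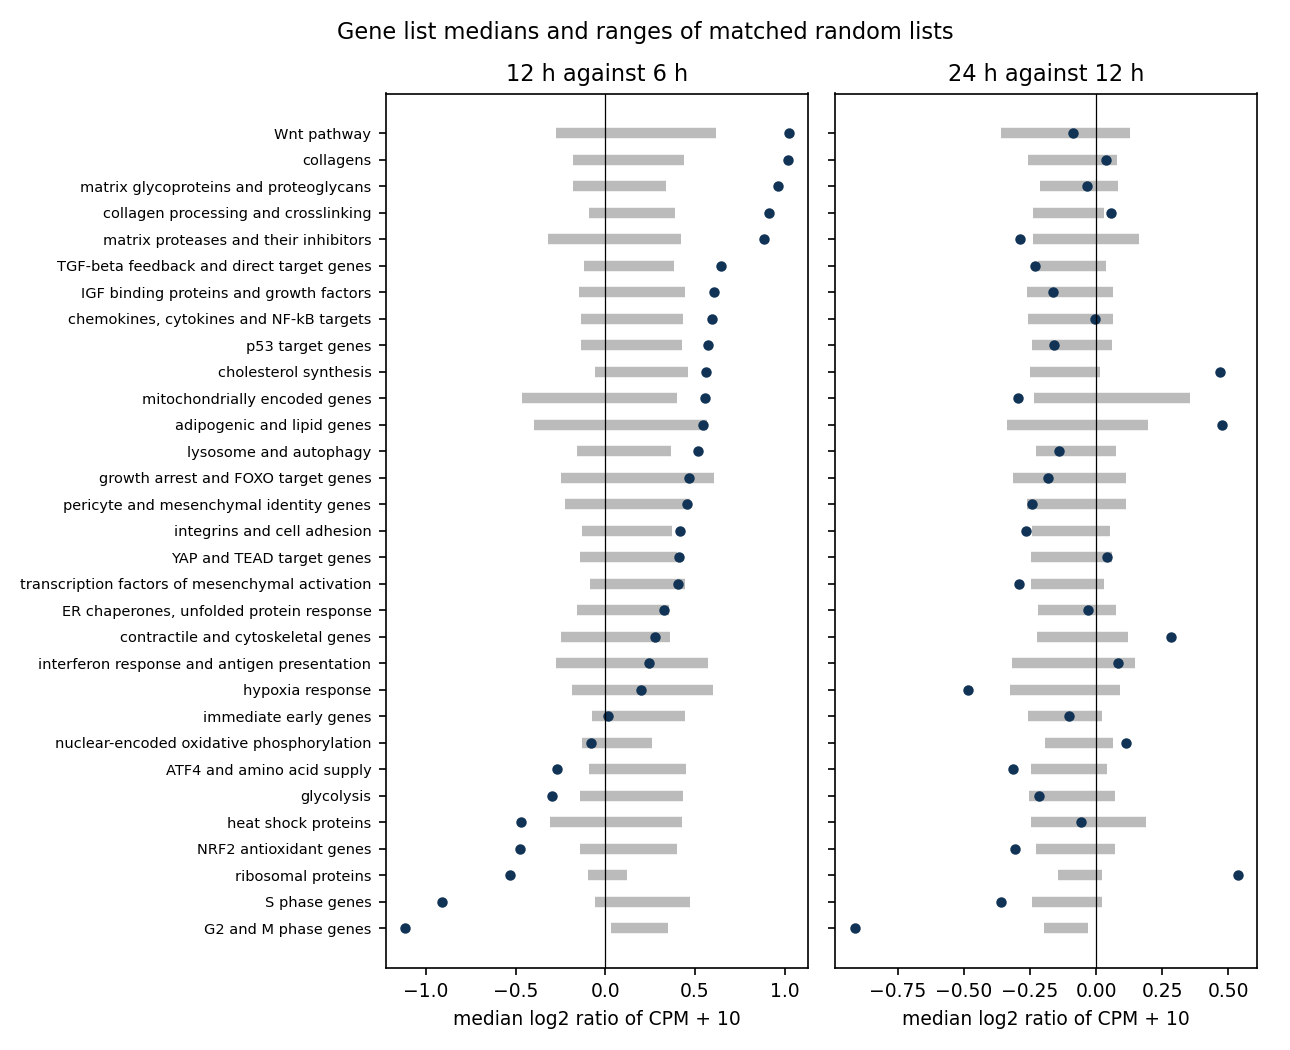
Median log2 ratio of CPM + 10 for the gene lists with 5 or more measured members, at 12 h against 6 h and at 24 h against 12 h; points are list medians and grey bars hold the central 95% of matched random lists. Collagens lie at 1.02 and 0.04, and G2 and M phase genes at -1.12 and -0.91.

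The remaining lists were compared among treated libraries as well. At 12 h against 6 h, immediate early genes had a median of 0.01, interferon and antigen presentation genes 0.24, hypoxia genes 0.20, complement genes 0.40 from 3 members, growth arrest and FOXO targets 0.46, chaperones of the endoplasmic reticulum 0.33, heat shock proteins -0.47, nuclear-encoded oxidative phosphorylation -0.08, pericyte and mesenchymal identity genes 0.46, mesenchymal transcription factors 0.41, adipogenic genes 0.54 and BMP pathway genes -0.06. The hypoxia, growth arrest, chaperone, interferon, complement, immediate early, oxidative phosphorylation, identity, transcription factor, adipogenic and BMP medians lay within the central 95% of matched random lists. Mitochondrially encoded genes had 0.56, but the median mitochondrial share per barcode went the other way, from 3.49% at 6 h to 2.32% at 12 h. In barcodes under 1000 counts at 6 h, 7 of 9 measured members were lower than in deeper ones, with a median of -1.63. Nuclear-retained RNAs had 1.80 from 3 members, of which Meg3 was 3.73-fold (3.31 to 4.20) and Neat1 3.68-fold (3.02 to 4.53) higher. Malat1, the other member, was 1.19-fold (1.16 to 1.22) higher, and its log2 ratio was 0.0030 in barcodes with 1000 or more counts. The Hedgehog list had 1 measured member, Smo, at 1.48-fold (0.909 to 2.54), and the skeletal list had Spp1, at 8.01-fold (2.17 to 66.9) from 2 counts at 6 h.

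In GRCm38, Fn1 lies on chromosome 1 at 71585520 to 71653200, Col3a1 on chromosome 1 at 45311538 to 45349706, Col1a2 on chromosome 6 at 4504814 to 4541544, and Acta2 on chromosome 19 at 34241090 to 34255590. Fn1 overlaps Apol7d on the other strand, and Col1a2 and Col3a1 each overlap a predicted gene on their own strand. Ctgf, a matricellular TGF-β target, was at 395 CPM at 6 h, 701 CPM at 12 h and 601 CPM at 24 h. Tagln, a smooth muscle actin-binding protein whose gene overlaps Pcsk7 on the other strand, was low throughout, at 11.6 CPM (5.28 to 21.9), 2.99 CPM (1.74 to 4.79) and 10.1 CPM (7.71 to 12.9). Postn had no count at 6 h, 5 at 12 h and 4 at 24 h. The receptor gene Pdgfrb was at 11.6, 41.1 and 45.1 CPM, and Pdgfra at 23.1, 30.9 and 19.5 CPM. Gli1 was not analysed here.

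Shares of barcodes with a count were compared after each barcode was thinned to 500 counts, which left 91, 134, 962 and 1003 barcodes and left out 101, 524, 158 and 325. Fn1 was counted in 0 of 91 barcodes of the library labelled 0 h, with an upper limit of 3.97%, in 23.9% (16.9 to 32.0) at 6 h, 74.1% (71.2 to 76.9) at 12 h and 80.3% (77.7 to 82.7) at 24 h. Thinned to 1000 counts, its shares were 52.5% at 6 h and 91.2% at 12 h, and thinned to 2000 counts, with 50 barcodes left at 6 h, 72.0% and 98.4%, so the gap narrowed with depth. Before thinning the shares were 13.8%, 91.4% and 85.5% at 6, 12 and 24 h. Nupr1 was counted in 11.9% (6.98 to 18.7), 47.2% (44.0 to 50.4) and 62.3% (59.2 to 65.3), and Prl2c2 in 54.5% (45.7 to 63.1), 45.0% (41.8 to 48.2) and 19.3% (16.9 to 21.9). Acta2 was counted in 20.1% (13.7 to 27.9), 4.37% (3.16 to 5.86) and 14.1% (12.0 to 16.4). For Mki67 the shares were 3.73% (1.22 to 8.49), 2.49% (1.60 to 3.69) and 0.399% (0.109 to 1.02), so a difference between 6 and 12 h was not detectable at this depth. Thinned to 1000 counts, which left 80 barcodes at 6 h and 865 at 12 h, Mki67 was counted in 13.8% (7.07 to 23.3) and 4.74% (3.42 to 6.38). Before thinning these shares were 15.3%, 84.6% and 85.0% for Nupr1, 63.7%, 79.4% and 52.0% for Prl2c2, 19.1%, 22.7% and 37.1% for Acta2, and 4.71%, 10.3% and 1.05% for Mki67. The intervals of these shares take each barcode as a separate cell. Since 257 barcodes at 12 h and 277 at 24 h lay 1 base from another, some cells may count more than once, and the intervals may be too narrow. No cell type that should lack these genes was found in the treated libraries, so the share due to free RNA was not measured.

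Clustering of all barcodes gave 8 clusters. Of these, 1 cluster held all 192 barcodes of the library labelled 0 h with 17 others, and Acsm2, Slc34a1, Slc12a1 and Kap led it. Hmmr, Mki67 and Cenpf led a cluster of 154 barcodes, of which 39 came from 6 h, 105 from 12 h and 10 from 24 h. A cluster of 18 barcodes, all from 6 h, had a median of 15563.5 counts and was led by Xirp2, Psph, Prl2c2 and Acta2. These genes were lower at 12 h than at 6 h in summed counts, which weigh such deep barcodes most. How much of those differences came from these 18 barcodes was not measured. The other clusters followed library and depth, so that cluster sizes were not compared between time points, and no cluster was given a cell type name.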

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

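The alternatives with barcodes of 1000 or more counts, without genes sharing 3′ sequence, and every alternative of the comparison of 24 h with 6 h were chosen after the data were examined, as was the use of the lists and named genes among treated libraries. Of 192 counts of genes under an alternative, 140 were within 1.5 times the reported count and 52 were not. Of 2904 list medians under an alternative, 6 turned sign from a reported size of 1.5-fold or more, and a further 778 lay outside the counting interval of the reported value. Of 3214 log2 ratios of named genes, 10 turned sign in this way and 1178 lay outside that interval, as did 195 of 308 shares of barcodes. No paired analysis was possible because each time point has 1 library. Leaving out the barcode filter removed no barcode and tests nothing, and keeping only clusters without markers of other cell types left no barcode of the library labelled 0 h, so those comparisons have no value there.

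The floor and the size limit moved the counts because they set how many genes are counted. With a floor of 50 CPM, higher and lower genes numbered 2223 and 1625 at 6 h, 2394 and 1469 at 12 h, and 2214 and 1564 at 24 h against the library labelled 0 h. Among treated libraries they numbered 211 higher at 12 h against 6 h, 38 lower at 24 h against 12 h, and 186 and 144 at 24 h against 6 h. With a floor of 200 CPM they were 774 and 425, 818 and 409, and 768 and 426 against the library labelled 0 h, 53 and 50 at 12 h against 6 h, 7 lower at 24 h against 12 h, and 55 and 42 at 24 h against 6 h. Genes differing at 6 h but not 24 h numbered 114 and 17 at the floors of 50 and 200 CPM, the reverse 86 and 17, genes lower throughout 1392 and 396, and genes higher throughout 869 at 200 CPM. With a 1.5-fold limit the counts were 362 and 232 at 12 h against 6 h, 94 and 79 at 24 h against 12 h, and 304 and 252 at 24 h against 6 h. A pseudocount of 50 shrinks ratios by construction and left 47 and 62, 3 lower, and 68 and 54. Leaving out genes that share 3′ sequence, which takes genes away, left 63 lower at 12 h against 6 h and 18 higher at 24 h against 12 h.

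Scaling and the choice of barcodes moved other counts, and the cause was not tested. DESeq2 size factors gave 58 higher and 155 lower genes at 12 h against 6 h, and DESeq2 and TMM each gave 7 lower at 24 h against 12 h. Equal weight per barcode gave 302 higher at 12 h and 217 at 24 h against 6 h. Without the tenth of barcodes with the most counts there were 346 higher and 153 lower at 12 h against 6 h, and 263 higher at 24 h against 6 h. The stricter barcode filter gave 1515, 1469 and 1543 lower genes at 6, 12 and 24 h against the library labelled 0 h, with 1402 lower throughout. Thinned to the total of the shallowest library, which adds counting noise, the libraries gave 291 and 176 at 12 h against 6 h, 100 and 205 at 24 h against 12 h, and 256 and 210 at 24 h against 6 h.

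Reversed log2 values were few. In barcodes without cell cycle counts, which by construction lack the cycle genes at the thinned depth, S phase and G2 and M phase medians were 0.19 and 0.12 at 12 h against 6 h and 0.027 and 0.0067 at 24 h against 6 h. There Mki67 had 0.90 and 0.29, Nusap1 0.13 at 12 h and Prc1 0.48 at 24 h against 6 h. In the same barcodes Ccl5 had 0.16 at 24 h against 6 h and the skeletal list 0.47 at 24 h against the library labelled 0 h, where the reported barcodes gave -0.86; the cause was not tested. Ap3s2 had 0.89 at 12 h and 0.48 at 24 h against 6 h with the stricter filter, and 0.88 and 0.46 in barcodes with 1000 or more counts, so its difference came from shallow barcodes. Vegfa had 0.22 at 24 h against 12 h when thinned, from few counts. The hypoxia list had -4.11 at 6 h against the library labelled 0 h with members at 50 CPM, against 0.59 with members at 20 CPM, since fewer members enter. The depth of the library labelled 0 h limits every comparison with it, as a gene without a count there is bounded only at 28.1 CPM.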

Other observations

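The tests of the 6 h level against shallow barcodes and against longer TGF-β, of the library labelled 0 h against the state of cultured cells, and of the dip at 12 h against shallow barcodes were chosen after the result was seen, as were the comparison of 24 h with 6 h and the groups of time courses below. The counting intervals set beside the tests were added after their values were seen.

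Most of the large differences among treated libraries lay between 6 and 12 h, an interval that also spans a large difference in depth. Genes at least 2-fold higher and lower numbered 108 and 98 there, against 29 and 15 from 12 to 24 h. Thinned to the total of the shallowest library, which adds counting noise, they numbered 291 and 176, against 100 and 205. Of 2313 genes at 100 CPM or more in a treated library, 97 were at least 2-fold higher at 12 h than at 6 h and within 1.5-fold of that level at 24 h, and 34 were lower and stayed so. A slower course, at least 2-fold from 6 to 24 h without a 2-fold step in either interval, was seen for 41 genes upward and 34 downward.

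Several smaller lists differed between 6 and 24 h. NRF2 antioxidant genes had a median log2 ratio of -0.62, below all matched random lists, with 8 of 16 members at least 1.5-fold lower, among them Nqo1 at 9.27-fold (6.16 to 14.0) and Txnrd1, a thioredoxin reductase, at 2.78-fold (2.52 to 3.07). ATF4 and amino acid supply genes had -0.52, also below all of them, with 7 of 15 members lower and 1 higher, and Psat1 was 6.42-fold (4.49 to 9.15) and Asns, asparagine synthetase, 3.18-fold (2.46 to 4.09) lower. Lysosome genes had 0.62, above the central 95% of matched random lists, with 9 of 17 members higher, among them the sterol carrier Npc2 at 2.55-fold (2.40 to 2.70), and cholesterol synthesis was higher too, with Hmgcs1 at 3.26-fold (2.22 to 4.98). Chemokines, cytokines and NF-kB targets had 0.85, above all matched random lists, with 7 of 13 members higher and 3 lower. Ccl2 was 3.18-fold (2.34 to 4.42) higher and Ccl5 9.19-fold (5.53 to 15.4) lower, a direction that turned to a log2 ratio of 0.16 in barcodes without cell cycle counts. Igfbp3 and Igf1 were 3.00-fold (2.39 to 3.83) and 1.97-fold (1.64 to 2.39) higher, while the median of their list, 0.12, lay within its random lists.

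The content of the library labelled 0 h is a pattern in 1 library. Its low share of ribosomal protein transcripts, 0.355%, argues against the state of the same cultured cells before TGF-β, and of the 100 highest genes of the 24 h library 9 had no count in it, against 0 when the 24 h library was thinned to its total. The split of tubule markers over its barcodes was set against a single mixed source of free RNA. In the 142 barcodes with 5 or more such counts, the variance of the loop share was 3.84 times the binomial variance. In 1000 draws of one mixture it reached at most 1.36. These draws take every count as independent. Whether UMIs were collapsed is not stated, and repeated counts of 1 molecule would also raise the variance. The values argue against a single mixed source only if counts are separate molecules. Cells or nuclei of a kidney tissue sample under this label remain a candidate explanation. Of the 142 barcodes, 59.2% (50.6 to 67.3) had at least 80% of their tubule counts from 1 list, 79 mostly proximal and 5 mostly loop. The same draws of one mixture gave a mean of 40.8% and at most 52.1%. The share of 59.2% was below the 80% set for separate cells. It was also just under the bound set against this explanation, but its interval reached above that bound. The explanation is left open for that reason. Several sources of free RNA, or free RNA mixed with cells, were not tested.

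The lower matrix transcripts at 6 h may have several sources. Shallow barcodes with free RNA or debris, whose collagen median log2 ratio to deep barcodes was -1.55 at 6 h, remain open: among barcodes with 1000 or more counts the collagen median at 12 h against 6 h was 0.74 (0.57 to 0.99), against 1.02 in all barcodes. The same shallow barcodes had -1.63 for mitochondrially encoded genes, -1.42 for matrix glycoproteins and -0.79 for chaperones of the endoplasmic reticulum. Ribosomal protein genes had 0.39 in them, and the median of all genes was -0.05. More cycling cells at 6 h also remain open, with 0.58 (0.34 to 0.94) in barcodes without a cell cycle count, of which the 6 h library had 27. For both tests, a median of 0.58 or more had been set as the value against the explanation. Both medians met that bound, so the point values alone would have counted against both explanations. Their counting intervals, added after the values were seen, reached below the bound, and both are left open for that reason. Longer exposure to TGF-β, the biological explanation the design gives, has the median of 1.02 but cannot be told apart from more hours in culture without serum, since no untreated culture was sampled at these hours.

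The dip at 12 h, in 27 genes such as Sec61g, Atp5l, Rpl35 and Acta2, did not need the shallow barcodes at 6 and 24 h. All 27 were still at least 1.5-fold lower at 12 h than at both in barcodes with 1000 or more counts. Those barcodes held 74.1%, 97.8% and 97.6% of the counts at 6, 12 and 24 h. Since the 27 genes were chosen from the same counts, that test had little room to fail. Reads shared with pseudogenes or paralogs, counted in another way in the 12 h library, remain a candidate explanation. Of 26 of these genes that could be searched, 42.3% shared at least 20% of their last 600 bases with another gene, against 13.1% of 2280 other genes, between the bounds set for this test. With any shared 51-mer the shares were 80.8% and 23.9%, but the median dip on the log2 scale was only -0.07 in the 189 genes with at least 50% shared, against 0.13 in genes with none and -0.55 in ribosomal protein genes, of which 68.8% shared at least 20%. No biological explanation was tested, since the design names none for a dip at a middle time point.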
